A study of Mus musculus with 4 samples.

How the data were processed

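The samples were 4 single-nucleus RNA libraries from mouse spleen. Per the labels, leukaemic B cells of the Eµ-TCL1 model (TCL1 cells) with or without Tbx21 had been grown in NSG mice, which lack lymphocytes of their own. Per the labels' protocols, splenocytes were enriched for TCL1 cells with a B cell isolation kit to a stated purity above 97%, and libraries were made with the joint chromatin accessibility and gene expression chemistry of 10x Genomics. Only the gene expression part was used here. The labels gave 2 libraries as Tbx21-WT and 2 as Tbx21-KO, numbered 1 and 2 in each group. They did not say whether the libraries of a group came from separate leukaemias, so that p-values measure the spread between these libraries, which may be less than that between independent leukaemias.

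The deposited files are unfiltered matrices of raw UMI counts, with 32285 genes and 736320 barcodes per library. Per the submitters' processing notes, Cell Ranger 5.0.0 and the mm10 build were used. Whether intronic reads were counted is not given in the sources used here. The counts were not normalised. Positions come from the GENCODE annotation of the same mouse build, in which 32235 of the 32285 gene identifiers were found, and 13037 of the 13041 tested genes had a position.

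Nuclei were barcodes with at least 500 UMIs, at least 300 genes and at least the 99th percentile of UMIs among the 3000 largest barcodes of the library divided by 10. That minimum was 6263 and 5590 UMIs in the Tbx21-WT libraries and 7212 and 4633 in the Tbx21-KO libraries, and it kept 1148, 1219, 825 and 1566 barcodes. It is strict, because a long tail of very large barcodes raised the percentile, and 3032, 4610, 4613 and 4104 barcodes held at least 1000 UMIs. Barcodes of so many UMIs can be multiplets of several nuclei, so alternatives with other limits were run. Nuclei with a mitochondrial percentage above the library's median plus 3 scaled median absolute deviations were left out. Scrublet, as run in scanpy 1.11.5, then marked 5, 16, 0 and 2 nuclei as doublets, which were removed. So few marks mean that doublets were in practice left untreated, and multiplets of 1 cell type cannot be found this way. The remaining nuclei numbered 1132, 1180, 818 and 1558.

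Nuclei were clustered on log-normalised counts of 2000 variable genes without immunoglobulin genes, with 30 principal components, 15 neighbours and the Leiden algorithm (leidenalg 0.10.2, resolution 0.5). A cluster was left out of the TCL1 nuclei when at least 3 markers of other cell types, and more of these than of B cell markers, were among its 50 leading genes by fold. This rule was set after the clusters had been seen. The marker lists had been fixed before. The clusters left out were an erythroid cell-like cluster, a plasma cell-like cluster and an unnamed cluster led by Adgre4, Trps1 and Slc8a1. The other 7 clusters are called TCL1 nuclei after the labels, and Ighm and Ebf1 were each seen in at least 99.9% of these nuclei in every library. This does not set them apart, because Ighm was also seen in 100% of nuclei of the unnamed cluster. It was seen in 73.7% and 94.7% of erythroid cell-like nuclei as well. B cell markers differed between the 7 clusters, with Cr2 among the 50 leading genes of cluster 1, Cd79a of cluster 2 and Bach2 of cluster 3. In 2 of these 7 clusters a marker of another type, Bst2 or Jchain, was among the 10 leading genes while no B cell marker was, so an alternative with all called nuclei is given. Different clusters held most TCL1 nuclei of the groups. Clusters 0 and 1 held most nuclei of the Tbx21-KO libraries, clusters 2 and 4 most of Tbx21-WT replicate 1, and clusters 3 and 5 most of Tbx21-WT replicate 2.

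UMI counts were summed per library over the TCL1 nuclei, giving 17119700, 14546200, 16509300 and 17159600 counts (to 6 digits). The sums were tested with edgeR 4.0.16 (R 4.3.3), with TMM normalisation, filterByExpr, a quasi-likelihood fit and a two-sided F test with Benjamini-Hochberg adjustment at 0.05. Differences are Tbx21-KO minus Tbx21-WT on the log2 scale. CPM of the gene tests were computed from the deposited counts with TMM library sizes. CPM of erythroid cell-like nuclei, the unnamed cluster and free RNA used raw UMI sums without TMM. The same holds for Ighm, Ebf1, Jchain and Xist in TCL1 nuclei where these are compared with them. The standard error of a log2 fold change was taken as its size divided by the square root of F. Means are given with SD over 2 libraries. On counts simulated from the means and sizes of these libraries, the test called 38 of 98 genes changed by 1 on the log2 scale, 88 of 97 changed by 2, and 11 of 12637 unchanged genes, among 12832 genes run.

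Gene lists (19 of programmes and 13 of cell type markers) were fixed before the data were examined, as were the tests and most alternatives. The 27 lists with at least 3 tested members were tested with camera (limma 3.58.1) at a correlation of 0.01 and, beside it, with an estimated correlation and with fry. The genes named in the text are Tbx21, the 10 with the largest log2 fold change in each direction, and up to 4 members of each list with the smallest p and a mean CPM of at least 5. The 10 in each direction were chosen among genes past the adjusted threshold whose libraries of 1 group all lay above those of the other, with a mean CPM of at least 20, without immunoglobulin, predicted and mitochondrial genes. Genes named outside this rule are said to be so.

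For shares of nuclei, each nucleus was thinned to 1000 UMIs and counted when at least 3 UMIs fell on a list. Intervals are exact (Clopper-Pearson) 95% binomial intervals and cover counting error only. Groups were compared by an exact two-sided permutation test, which with 2 against 2 libraries cannot give a p under 0.333. Free RNA was taken from barcodes of 50 to 250 UMIs. Alternatives were other normalisation (RLE), DESeq2 1.42.0, no filter on low counts, other limits on UMIs and mitochondrial percentage, doublets kept, all called nuclei, no abundant genes, thinning, blocks by replicate number and leaving out each library. The chromatin accessibility data were not used here.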

Results

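Gene expression was measured in single nuclei of TCL1 leukaemia cells, B cells that carry the TCL1 oncogene and form a disease like chronic lymphocytic leukaemia in mice. The series asked how T-bet, the transcription factor encoded by Tbx21, acts on malignant B cells. The 4 spleen libraries comprised 2 labelled Tbx21-WT and 2 labelled Tbx21-KO. Total depth was 37409144 and 42440604 UMIs in the Tbx21-WT libraries and 40187076 and 35620295 in the Tbx21-KO libraries. TCL1 nuclei numbered 1119 and 1141 in the Tbx21-WT libraries and 777 and 1467 in the Tbx21-KO libraries. Their median depth was 10091, 8712, 12457 and 7511 UMIs in the same order. The mitochondrial share of their UMIs, a sign of RNA quality, had medians of 21.4% and 17.5% in the Tbx21-WT libraries and 29.7% and 25.4% in the Tbx21-KO libraries, so it moved with the genotype label. Expression correlated more closely within a genotype (Pearson r across genes of 0.978 for Tbx21-WT and 0.990 for Tbx21-KO) than between genotypes (0.947 to 0.957). Genes are not independent replicates in such a correlation. Counts of every pair of libraries differed by more than sampling noise. The chi-square per degree of freedom was 19.8 between the Tbx21-KO libraries and 66.9 between the Tbx21-WT libraries. Between genotypes it ran from 69.03 to 113.5. By this measure the Tbx21-WT libraries differed nearly as much as the closest pair of different genotype.

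Tbx21 transcripts were present at similar levels under both labels. The gene (ENSMUSG00000001444, chromosome 11, 97098071 to 97115331 of mm10, minus strand) gave 11.1 and 13.8 CPM in the Tbx21-WT libraries and 12.98 and 9.78 CPM in the Tbx21-KO libraries. The group means were 12.5 ± 1.9 CPM (SD, n = 2) for Tbx21-WT and 11.4 ± 2.3 CPM (SD, n = 2) for Tbx21-KO. The log2 fold change was -0.13 with a standard error of 0.24 (edgeR adjusted p = 0.806). At a common depth of 4000 UMIs, Tbx21 was seen in 4.65% (95% interval 3.49 to 6.05) and 5.78% (4.50 to 7.30) of TCL1 nuclei under the Tbx21-WT label, and in 4.25% (2.94 to 5.91) and 3.41% (2.54 to 4.47) under the Tbx21-KO label. Without thinning the shares were 13.1%, 14.3%, 18.3% and 8.93% in the same order of libraries. In the erythroid cell-like nuclei, which should lack the gene, the shares at 4000 UMIs were 1 of 19 and 1 of 57 nuclei. These nuclei also held RNA of the B cell gene Ebf1, at 1778 and 1611 CPM, so they are no clean reference. In free RNA Tbx21 had 6.36 and 7.97 CPM in the Tbx21-WT libraries and 8.36 and 3.35 CPM in the Tbx21-KO libraries, so part of its UMIs in nuclei can be background. The labels do not say which part of the gene was deleted, and reads outside that part can remain, so Tbx21 neither checks nor contradicts the labels here. All directions below therefore rest on the labels, and the groups are called KO-labelled and WT-labelled libraries.

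The genotype labels separated many genes of the TCL1 nuclei. Foxp2, a forkhead transcription factor, had a mean of 49.1 ± 17.1 CPM (SD, n = 2) in the KO-labelled libraries against 0.246 ± 0.097 CPM (SD, n = 2) in the WT-labelled libraries, where it rested on 8 UMIs in all. Bmpr1a, a receptor for bone morphogenetic proteins, rose from 2.65 ± 0.16 to 93.4 ± 14.6 CPM, and Rras2, a small GTPase related to Ras, from 2.77 ± 0.18 to 66.2 ± 2.8 CPM (SD, n = 2 each). The TNF family ligands Tnfsf8 and Tnfsf15 rose from 1.87 to 52.4 CPM and from 2.23 to 38.4 CPM. In the opposite direction, Sult5a1, a sulfotransferase, fell from 150.2 ± 71.8 to 11.1 ± 0.16 CPM, and Parm1 from 202.1 ± 15 to 31.5 ± 1.1 CPM. The calcium-binding proteins S100a4 and S100a6 also fell, but their levels differed about 4-fold between the WT-labelled libraries, at 147.9 and 33.6 CPM for S100a4 and 1092 and 258 CPM for S100a6.

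**Figure D1:**
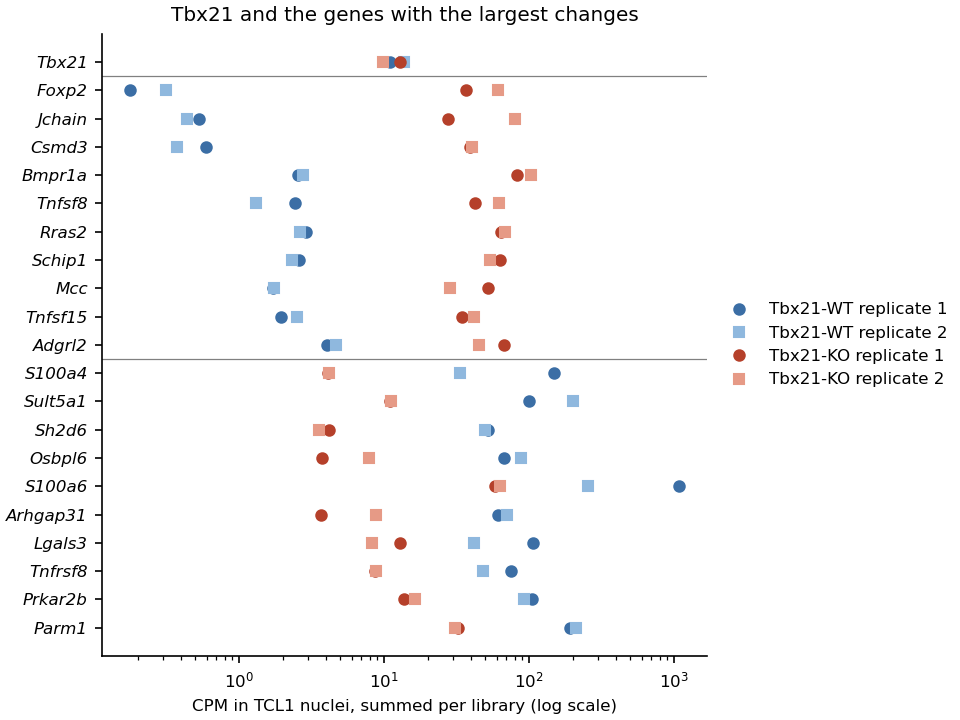
CPM of Tbx21 and of the 10 genes with the largest change in each direction, 1 point per library, on a log axis (blue, WT-labelled; red, KO-labelled). Tbx21 lies between 9.78 and 13.8 CPM in all 4 libraries. The other genes were chosen among those whose points fall apart by label, so their separation is set by the choice.

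By edgeR, 881 of 13041 tested genes passed an adjusted p of 0.05, of which 494 were higher and 387 lower in the KO-labelled libraries. The largest increases after Foxp2 (log2 fold change 7.61, SE 0.43, adjusted p = 0.000973) were those of Jchain (6.78, SE 0.67, with 54.2 ± 37.4 CPM, SD, n = 2, on 435 and 1344 UMIs in the KO-labelled libraries), Csmd3 (6.34), Bmpr1a (5.14), Tnfsf8 (4.79), Rras2 (4.58), Schip1 (4.57), Mcc (4.53), Tnfsf15 (4.10) and Adgrl2 (3.68). The largest decreases were those of S100a4 (log2 fold change -4.45, SE 0.70, adjusted p = 0.0195), Sult5a1 (-3.76), Sh2d6 (-3.73), Osbpl6 (-3.73), S100a6 (-3.48), Arhgap31 (-3.39), Lgals3 (-2.81), Tnfrsf8 (-2.81), Prkar2b (-2.72) and Parm1 (-2.68). Foxp2 lies on chromosome 6 (14901349 to 15441977) and Bmpr1a on chromosome 14 (34410734 to 34503341). Sult5a1 lies on chromosome 8 (123140192 to 123158315) and S100a4 and S100a6 on chromosome 3 (from 90603771 and from 90612882), in mm10. In all 881 genes both libraries of 1 label lay above both of the other. This held for 51.6% of all tested genes, against 33.3% by chance. The count of genes depended on each library. It was 2504 without WT-labelled replicate 1, 4051 without WT-labelled replicate 2 (1835 higher and 2216 lower, so that the balance turned), 240 without KO-labelled replicate 1 and 267 without KO-labelled replicate 2, with the lone library assumed to vary like the other group.

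Genes of the cell division cycle were higher in the KO-labelled libraries. Of 58 tested S phase genes, 17 rose, none fell and 41 did not pass, and 41 rose when adjusted over the list alone. Clspn, which signals replication stress, rose from 41.2 ± 6.0 to 93.5 ± 7.8 CPM (SD, n = 2), and Dtl, Pole and Brip1 rose 2.18-fold, 2.09-fold and 1.79-fold in mean CPM. Of 66 tested G2/M genes, 16 rose and none fell (43 rose when adjusted over the list alone). Cdca2 rose from 24.9 ± 3.4 to 54.1 ± 3.1 CPM, Psrc1, also regulated by p53, from 4.58 ± 0.88 to 39.7 ± 5.2 CPM, and Ncapd2 and Kif15 1.78-fold and 1.81-fold. The proliferation marker Mki67, chosen after its values were seen, rose from 236 ± 53 to 478 ± 86 CPM. The median log2 fold change was 0.71 for the S phase list and 0.58 for the G2/M list, and 57 of 58 and 65 of 66 members were higher. By camera both lists passed (adjusted p = 1.1e-15 and 8e-15), and neither did with an estimated correlation (p = 0.163 and 0.127, adjusted p = 0.949 for both). Mitochondrial percentages were higher in the same libraries, as given above.

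**Figure D2:**
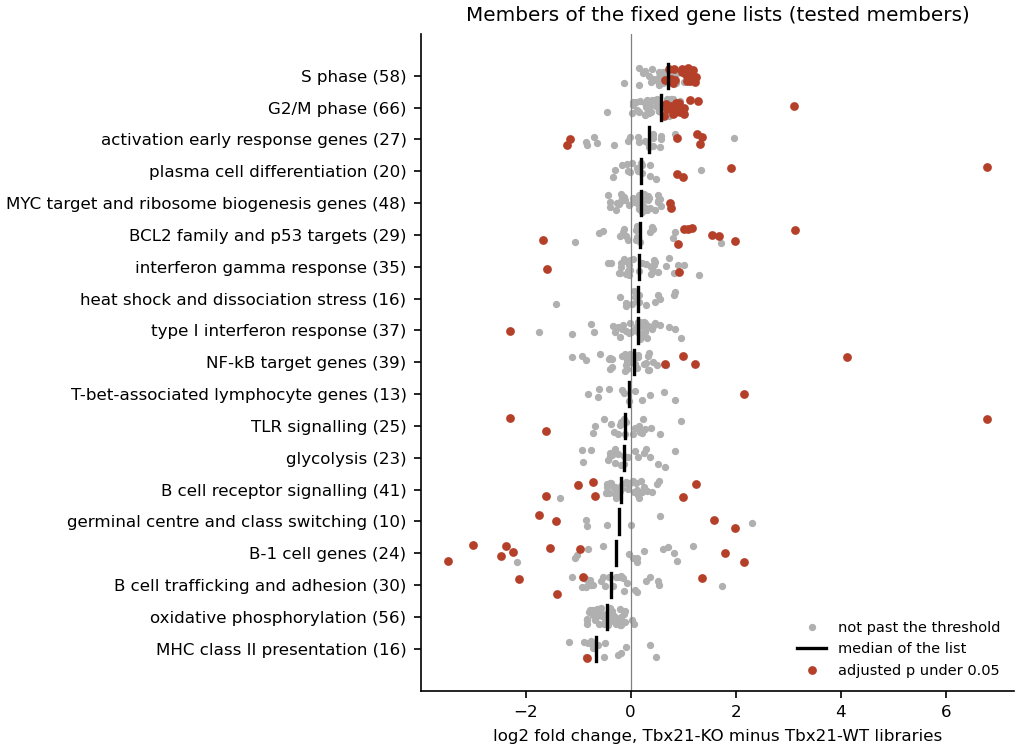
log2 fold change (KO-labelled minus WT-labelled) of the tested members of the 19 programme lists, 1 point per gene, with the number tested in brackets. Black bars are list medians and red points passed an adjusted p of 0.05, with 17 of 58 S phase and 16 of 66 G2/M genes on the right of 0.

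Targets of p53 and genes of cell death moved in part. Of 29 tested members of the BCL2 family and p53 list, 8 rose and 1 fell. The death receptor Fas rose from 5.25 ± 0.85 to 20.9 ± 1.8 CPM, Zmat3 2.24-fold and the nuclease Aen 1.87-fold. Cdkn1a, Pmaip1, Phlda3, Tnfrsf10b and Gtse1, named after their values were seen, rose as well, Cdkn1a from 8.08 ± 2.11 to 23.5 ± 4.9 CPM. Bcl2l11, which encodes the pro-apoptotic protein Bim, fell from 68.0 ± 18.1 to 21.3 ± 2.0 CPM. The list passed by camera (adjusted p = 0.0114) but not with an estimated correlation (adjusted p = 0.949).

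Genes of B cell identity and signalling went both ways. Of 24 tested B-1 cell genes, 2 rose and 7 fell. Sox5 fell from 547 ± 68 to 99.5 ± 17.3 CPM, Ahnak from 739 ± 208 to 255 ± 14 CPM, and S100a6 as above. The transcription factor Bhlhe40 rose 3.46-fold, and the receptor-like protein Fcrl5 rose from 34.6 ± 1.3 to 154.2 ± 7.5 CPM. Fcrl5 was also the 1 call among 13 tested genes of the T-bet-associated list, in which Fcrla (adjusted p = 0.0605), Ifngr1 (0.145) and Zeb2 (0.230) did not pass in edgeR. Among 41 genes of B cell receptor signalling, 2 rose, Cr2 2.36-fold and the kinase Fyn 1.98-fold, and 4 fell. Among these 4, Pik3r1 fell from 224 ± 23 to 112 ± 4 CPM and the inhibitory receptor Lilrb4a from 106 ± 32 to 34.8 ± 8.9 CPM. Of the 15 B cell markers, Cr2 rose, Bach2 and Cd22 fell, and 12 did not pass. Of 27 early response genes of activation, 4 rose and 2 fell. Egr1 rose from 181 ± 4 to 452 ± 19 CPM, Nr4a1 2.58-fold and Dusp6 2.40-fold, and Klf6 fell from 175 ± 37 to 78.2 ± 5.5 CPM. None of these lists passed by camera (adjusted p = 0.245 for B-1 cell genes, 0.885 for T-bet-associated genes and for B cell markers, 0.249 for B cell receptor signalling and 0.0704 for early response genes). The T-bet-associated list had a median log2 fold change of -0.02 and a mean of 0.12.

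Interferon, antigen presentation and NF-kB genes showed few calls. In the type I interferon list 1 of 37 genes passed, Irf7, which fell from 16.5 ± 3.7 to 3.35 ± 1.12 CPM, while Bst2 (adjusted p = 0.0631), Ifih1 (0.0582) and Ifi209 (0.121) did not pass in edgeR. In the interferon gamma list of 35 genes, Cd274, the gene of PD-L1, rose from 71.6 ± 9.8 to 135.4 ± 9.5 CPM and Irf8 fell from 158 ± 14 to 52.7 ± 6.5 CPM. Nlrc5 (0.0650) and Irf1 (0.0817) did not pass. Of 25 genes of Toll-like receptor signalling, Irak3 fell from 58.4 ± 1.9 to 19.1 ± 2.0 CPM, Irf7 fell, and Tlr3, named after its values were seen, rose from no UMI in either WT-labelled library to 0.834 CPM. In the MHC class II list 1 of 16 genes passed, H2-Ob, which fell from 149 ± 1 to 83.7 ± 1.8 CPM. The list was lower by camera (adjusted p = 0.0167, and 0.949 with an estimated correlation). Of 39 NF-kB target genes 4 rose and none fell: the cytokine gene Il10 rose 2.33-fold, Irf4 1.99-fold and the inhibitor Nfkbie 1.57-fold, and the chemokine gene Ccl22, named after its values were seen, reached 6.96 ± 4.33 CPM (SD, n = 2) on 61 and 167 UMIs in the KO-labelled libraries, and was among the 10 leading genes of a cluster of 34 TCL1 nuclei, 32 of them from KO-labelled replicate 2. By camera the type I interferon (adjusted p = 0.653), interferon gamma (0.0826), Toll-like receptor (0.711) and NF-kB (0.597) lists did not pass. Median and mean log2 fold change differed in sign for the type I interferon list (0.13 and -0.02) and the Toll-like receptor list (-0.10 and 0.09).

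Genes of plasma cells, germinal centres and trafficking also changed. Of 20 plasma cell differentiation genes, 4 rose (camera adjusted p = 0.0285, and 0.949 with an estimated correlation). They were Jchain, Derl3 (3.77-fold), Irf4 and Prdm1, the gene of Blimp-1 (1.85-fold). Jchain was seen, at 4000 UMIs, in 6.95% (5.26 to 8.97) and 16.8% (14.9 to 18.8) of TCL1 nuclei in the KO-labelled libraries, and in 2 of 19 (10.5%) and 7 of 57 (12.3%, 5.08 to 23.7) of their erythroid cell-like nuclei, of median depths 9503 and 8246 UMIs. Jchain was thus about as frequent in these few nuclei as in TCL1 nuclei of the same libraries. The erythroid cell-like nuclei also held B cell RNA, however. Their Ighm was at 1213 and 1449 CPM, against 1683 and 2023 CPM in the TCL1 nuclei. They are therefore no clean reference, and whether the rise comes from expression in TCL1 cells cannot be told from them. Of 10 germinal centre genes, Fas and Mybl1 (2.99-fold) rose, and Aicda, the deaminase of class switching, fell from 12.6 ± 3.5 to 3.75 ± 1.23 CPM, as did Ighg3 (camera adjusted p = 0.933, median log2 fold change -0.22 and mean 0.11). Of 30 trafficking genes, S1pr3 rose 2.56-fold and S1pr4, Itgb7 and Itga4 fell, Itga4 from 499 ± 53 to 266 ± 34 CPM (camera adjusted p = 0.0167 for the list, and 0.949 with an estimated correlation). Of 48 MYC target and ribosome biogenesis genes, Nop56 and Tfrc rose 1.69-fold each (camera adjusted p = 0.0211, and 0.949 with an estimated correlation), and without WT-labelled replicate 2 the direction of the list turned (adjusted p = 0.910). No gene passed in edgeR among 56 of oxidative phosphorylation, 23 of glycolysis and 16 of heat shock. The oxidative phosphorylation list had a median log2 fold change of -0.45 and was lower by camera (adjusted p = 0.00718, and 0.949 with an estimated correlation). Without WT-labelled replicate 1 the direction of that list turned (adjusted p = 0.0737).

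More nuclei of the KO-labelled libraries held transcripts of the S phase and G2/M lists. At 1000 UMIs per nucleus, 62.5% (95% interval 59.0 to 66.0) and 55.6% (52.97 to 58.1) of TCL1 nuclei in the KO-labelled libraries had at least 3 UMIs of the S phase list, against 39.8% (36.9 to 42.7) and 37.2% (34.4 to 40.1) in the WT-labelled libraries. The group means were 59.1 ± 4.9% and 38.5 ± 1.8% (SD, n = 2). For the G2/M list the shares were 74.9% (71.7 to 77.9) and 70.3% (67.9 to 72.6) against 47.8% (44.8 to 50.8) and 47.5% (44.6 to 50.4), with means of 72.6 ± 3.3% and 47.7 ± 0.2% (SD, n = 2). Both differences exceeded the spread between libraries of 1 label, and the exact permutation test gave p = 0.333 for each, the smallest value that 2 against 2 libraries allow. No nucleus was too shallow for thinning. The nuclei with 2 or 3 S phase UMIs, next to the limit, numbered 306, 379, 259 and 463 in the 2 WT-labelled and 2 KO-labelled libraries, so the classes are ranges and not types. Among TCL1 nuclei of at least 1000 UMIs, a setting chosen after seeing the data, the means were 48.9% and 27.5% for the S phase list and 58.1% and 33.5% for the G2/M list. Without thinning nearly every nucleus passed, with G2/M means of 99.8% in the KO-labelled and 99.9% in the WT-labelled libraries. Free RNA was richer in these lists in the KO-labelled libraries, at 7.22 and 8.07 G2/M UMIs per 1000 against 5.004 and 4.49, so the shares do not by themselves show cycling cells.

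**Figure D3:**
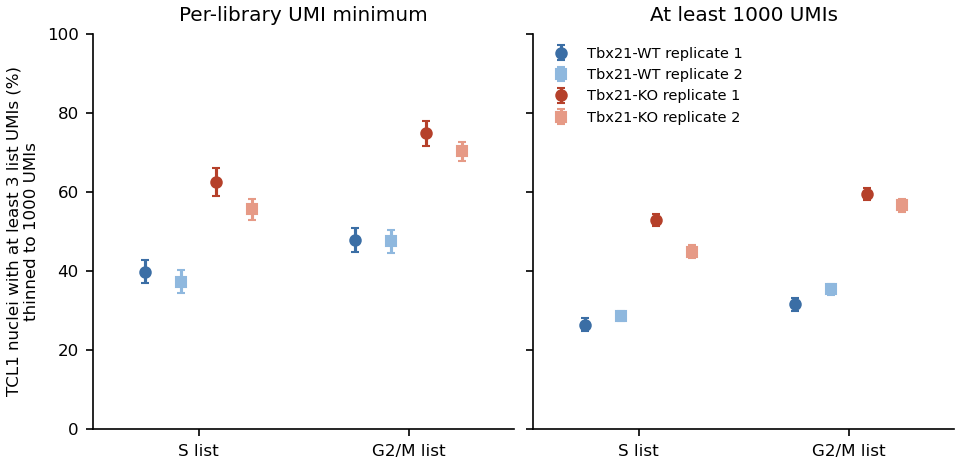
Share of TCL1 nuclei, thinned to 1000 UMIs, with at least 3 UMIs of the S phase or G2/M list, 1 point per library with its exact 95% binomial interval. Left, nuclei above the UMI minimum of their library; right, those of at least 1000 UMIs, a setting chosen after seeing the data. The KO-labelled libraries lie above the WT-labelled ones for both lists in both panels.

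Nuclei outside the TCL1 clusters were few after the B cell enrichment. An erythroid cell-like cluster with Car1, Car2, Ank1, Hba-a1, Hbb-bs and Tspan33 among its 50 leading genes held 76 nuclei, all in the KO-labelled libraries, at 2.32% (1.40 to 3.60) and 3.66% (2.78 to 4.71) of nuclei. The WT-labelled libraries had 0 of 1132 and 0 of 1180 nuclei in it, with upper 95% limits of 0.325% and 0.312%. Among barcodes of at least 1000 UMIs the cluster held 0 of 2996 and 4 of 4524 nuclei in the WT-labelled libraries and 77 of 4576 and 112 of 4053 in the KO-labelled libraries. With doublets kept the cluster so named held 1.06% and 3.01% of WT-labelled and 4.52% and 4.81% of KO-labelled nuclei, and with 2000 to 10000 UMIs 0.759% and 0.695% against 2.26% and 2.80%. In both of these settings no unnamed cluster formed, and Slc8a1, a leading gene of the unnamed cluster, was among the 10 leading genes of the cluster named erythroid cell-like. A plasma cell-like cluster with Jchain, Sdc1, Xbp1, Derl3 and Irf4 held 22 nuclei, again all in the KO-labelled libraries, at 0.733% (0.270 to 1.59) and 1.03% (0.588 to 1.66). Among barcodes of at least 1000 UMIs it held 1 of 2996 and 1 of 4524 WT-labelled nuclei. There it held 64 of 4576 (1.40%) and 75 of 4053 (1.85%) KO-labelled nuclei. Of the 22 nuclei above, 0 of 6 and 2 of 16 had Xist, against 100% and 98.2% of erythroid cell-like nuclei. Igkv4-91, a leading kappa segment of TCL1 nuclei, was seen in 2 of 6 and 14 of 16. In erythroid cell-like nuclei it was seen in 3 of 19 and 7 of 57. Whether the plasma cell-like nuclei are TCL1 cells with plasma cell expression or another cell type was not tested. The unnamed cluster, with Csf1r, Adgre1 and Fn1 among its 50 leading genes, held 1.15% and 3.31% of nuclei in the WT-labelled and 1.96% and 1.16% in the KO-labelled libraries. The B cell gene Ebf1 was seen in all nuclei of the unnamed cluster, at 2250 and 2809 CPM in the WT-labelled and 2730 and 2963 CPM in the KO-labelled libraries, close to its level in TCL1 nuclei (2490, 3025, 2811 and 3035 CPM). Xist was seen in 92.3%, 59.0%, 62.5% and 77.8% of these nuclei in the same order of libraries, against at most 3.86% of TCL1 nuclei, so these barcodes hold B cell RNA together with RNA that TCL1 nuclei nearly lack. Together the 3 clusters held 5.43 ± 0.59% of nuclei under the KO label and 2.23 ± 1.53% under the WT label (SD, n = 2, exact permutation p = 0.333, the smallest possible), and all of the WT-labelled share came from the unnamed cluster. The isolation kit and the UMI minimum both bear on these shares.

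Markers of other cells also moved within the TCL1 nuclei. Of 8 tested erythroid markers, Tfrc, Car1 and Car2 rose, and Car1 and Car2, named after their values were seen, reached 3.51 ± 2.08 and 3.43 ± 3.22 CPM (SD, n = 2) on 32 and 83 UMIs (Car1) and 18 and 95 UMIs (Car2) in the KO-labelled libraries. Of 8 macrophage markers, Vcam1 rose from 2.47 ± 0.32 to 14.5 ± 1.0 CPM, and Mrc1, named after its values were seen, rose 2.97-fold. Of 7 plasma cell markers 4 rose (camera adjusted p = 0.000802, and 0.949 with an estimated correlation). Single markers fell in other lists: Tcf7 of T cells from 80.8 ± 8.1 to 28.2 ± 4.7 CPM, Pecam1 of endothelium from 339 ± 78 to 155 ± 14 CPM, Ms4a6c of monocytes and Zbtb46 of dendritic cells, and Klrb1c of NK cells, named after its values were seen. The T cell list was lower by camera (adjusted p = 0.0211, and 0.949 with an estimated correlation), but only 4 of its 13 markers were tested and Tcf7 alone passed in edgeR.

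The leading immunoglobulin segments were the same in the 4 libraries. Ighv12-3 took 71.2% (66.8 to 75.4) and 64.2% (59.3 to 68.95) of heavy chain variable UMIs in the WT-labelled libraries and 72.1% (66.9 to 76.8) and 69.4% (65.0 to 73.5) in the KO-labelled libraries, of 333 to 477 UMIs each. Ighv5-6 and Ighv1-62-3 followed in all 4. Among kappa segments, Igkv4-91 and Igkv4-77 held the first 2 ranks in each library. Igkv2-107 followed in both KO-labelled libraries, at 11.8% (9.32 to 14.7) and 11.8% (9.78 to 14.0), against 1.47% (0.843 to 2.38) and 1.24% (0.569 to 2.34) in the WT-labelled libraries. Variable segments are close relatives of one another, so reads between them can be shared.

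**Figure D4:**
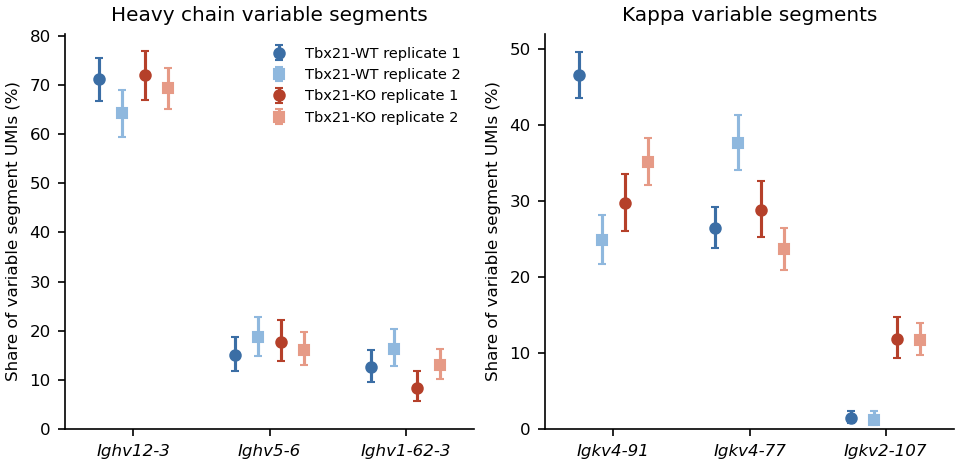
Share of heavy chain (left) and kappa (right) variable segment UMIs taken by the named segments in TCL1 nuclei, 1 point per library with its exact 95% binomial interval. Ighv12-3 takes between 64.2% and 72.1% in all 4 libraries, and Igkv2-107 is near 11.8% in both KO-labelled libraries alone.

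Chromosome-wide shifts between the labels were small. The median log2 fold change of a chromosome lay between -0.07 (chromosome X) and 0.08 (chromosome 13). Against 10000 random gene lists of the same size, chromosome 13 lay at percentile 100 and chromosome 17 at percentile 99.7, and chromosomes 7, 9, 3 and X lay at percentiles 0, 0.03, 0.2 and 0.2. Genes of a chromosome are not independent, so these percentiles can be too extreme. Around Tbx21, 20 of 252 tested genes within 10 Mb were called (7.94%), against 861 of 12785 elsewhere (6.73%; Fisher's exact test, two-sided, p = 0.446).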

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

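All tests in this part were chosen after the results had been seen, except those of Jchain against near-empty barcodes and between clusters, whose expected outcomes were written before their values were seen.

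Jchain and Robo1 were flagged because they stood out in near-empty barcodes of 50 to 250 UMIs, which are too small to be nuclei and are left out of the gene tests. Jchain reached 303 and 505 CPM there in the KO-labelled libraries, against 6.59 and 2.61 CPM in the WT-labelled libraries. Robo1 reached 101 and 112 CPM, against 2.39 and 5.07 CPM. These were the 2 genes with at least 100 CPM and a 10-fold gap between the labels, and none passed in the other direction. Robo1 rose in TCL1 nuclei as well, from 13.4 to 168 CPM (edgeR adjusted p = 0.000439), and was chosen after its values were seen.

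For Jchain in TCL1 nuclei, free RNA in the amount of a near-empty barcode brings too little, since nuclei of 2000 to 4000 UMIs held 2.43 and 2.69 times the Jchain UMIs of the median near-empty barcode in the KO-labelled libraries. In the WT-labelled libraries the ratios were 1.19 and 3.96, resting on 1 and 5 nuclei with Jchain. Such a ratio is therefore not particular to the KO label. A larger amount of free RNA in nuclei stays open as a part or the whole of the cause. Of 207 genes abundant in free RNA, the lowest lay at 2.91% and 4.26% of its free RNA level in TCL1 nuclei of these libraries. Jchain lay at a higher share of its own free RNA level (26.3 of 303 and 78.3 of 505 CPM). Such a bound on free RNA rests on 1 gene in each library, the lowest of 207, whose medians were 35.9% and 42.5%. Erythroid cell-like nuclei of the same libraries held Ighm at 26.7% and 22.9% of its free RNA level. B cell RNA can thus reach other nuclei in larger amounts than the bound allows, so the bound does not decide the question. The TCL1 cluster led by Jchain held 15.9% and 34.9% of the Jchain UMIs of TCL1 nuclei in the KO-labelled libraries, and 25.0% and 33.4% of the other TCL1 nuclei had Jchain, so this cluster is not the whole cause. A wider subset of TCL1 nuclei with plasma cell expression stays open: shares with Jchain differed only 1.28-fold and 1.15-fold between clusters, under the 1.5 set beforehand as speaking against a subset, but plasma cell-like and small clusters had been left out, which voids that test. Low expression in all TCL1 nuclei and multiplets with plasma cells were not tested.

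The rise of S phase and G2/M genes was weighed against 3 technical explanations. Mitochondrial content differed by label, but among nuclei of at least 1000 UMIs and at most 20% mitochondrial UMIs, which changes the UMI minimum as well, the lowest KO-labelled share still lay 20.4 percentage points above the highest WT-labelled share for the S phase list, the smaller of the 2 gaps. Among nuclei of 2000 to 10000 UMIs, which leaves out the largest barcodes, the smaller gap was 16.3 percentage points. Free RNA would have to make up at least 32.9% of a nucleus in KO-labelled replicate 1 and 36.8% in KO-labelled replicate 2 to bring the difference. This holds even with none in the WT-labelled libraries. Of 207 genes abundant in free RNA, 78 and 68 lay in TCL1 nuclei of the KO-labelled libraries below the share of their free RNA level needed in that library. Free RNA of the composition measured in near-empty barcodes is thus not the whole cause. Those barcodes held 2.48% and 1.79% mitochondrial UMIs in the KO-labelled libraries, against medians of 29.7% and 25.4% in TCL1 nuclei. Background RNA of another composition was not tested. A difference in cycling that goes with the label is a hypothesis, found and tested on the same data.

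The lower S100a6, S100a4, Crip1, Vim, Anxa2, Lgals3 and Emp3 were weighed against retained cytoplasmic RNA, because these genes also differed between the WT-labelled libraries (median log2 ratio 1.61), as ribosomal protein genes did (1.29). The median log2 fold change of ribosomal protein genes was 0.207 of that of the 7 genes, between the bounds set for either outcome. In 1 pair of libraries the 2 measures went apart. KO-labelled replicate 2 had a larger ribosomal share of UMIs than WT-labelled replicate 2 (3.46% against 2.76%). Yet it had fewer UMIs of S100a6 (1051 against 4105), Vim (2698 against 5735) and Anxa2 (446 against 1156). Because this is 1 library per label, retained cytoplasmic RNA and a change in expression cannot be told apart for the 7 genes.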

How the results depend on the processing

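Alternatives with nuclei of 2000 to 10000 UMIs, with both at least 1000 UMIs and at most 20% mitochondrial UMIs (here the mitochondrial limit with its lower UMI minimum) and with crossed numbers, and for the phase shares at least 1000 UMIs, were chosen after seeing the data. Every gene called both in the reported fit and in an alternative kept its direction. The count of 881 became 1475 with at least 1000 UMIs per barcode, 235 with equal nuclei of 1000 UMIs (103 higher and 132 lower), 1488 with 2000 to 10000 UMIs, 455 with the mitochondrial limit and lower UMI minimum, and 240 to 4051 in leave-one-out fits. Of the 70 named genes past the threshold none reversed. The threshold was missed by 40 without KO-labelled replicate 1 37 without KO-labelled replicate 2, 22 under the replicate block, 18 with the mitochondrial limit and lower UMI minimum, and 19 of 64 with equal nuclei. Libraries share only a number: the correlation of same-number deviations was -0.227, the replicate block gave 427 genes, and the crossed pairing gave 1608. Tbx21 had a log2 fold change of -0.34 to 0.0602 in leave-one-out fits and 0.19 with 2000 to 10000 UMIs (adjusted p = 0.738). Of 10 gene lists past the threshold by camera, 0 passed with an estimated correlation and 0 with fry. The MYC list ranged from an adjusted p of 8.4e-07 to 0.910 (direction down) in leave-one-out fits, and the oxidative phosphorylation list from 5.1e-14 to 0.0850, up without WT-labelled replicate 1, and up at 0.762 with the mitochondrial limit and lower UMI minimum. Directions of lists past the threshold in neither setting changed 29 times in 10 lists. Without thinning the G2/M difference was -0.073 percentage points, because nearly all nuclei passed. The unnamed cluster's difference was -1.75 to 0.407 points in leave-one-out values and 1.51 with at least 1000 UMIs, and no such cluster formed with doublets kept or with 2000 to 10000 UMIs. Igkv4-91 took 39.5% in KO-labelled replicate 2 with all called nuclei (414 UMIs against 331 in TCL1 nuclei, with 65 in plasma cell-like nuclei). Of genes not past the threshold, leave-one-out log2 fold changes were -0.17 to 0.0457 (Ccr9), -0.10 to 0.50 (Cd68), -0.17 to 0.12 (Col1a1), -1.35 to 0.0203 (Cox6b1), -1.82 to 0.0628 (Hbb-bt) and -0.52 to 0.44 (Plac8). With 2000 to 10000 UMIs Cd68 had -0.32 and Col1a1 0.14, with at least 1000 UMIs Col1a1 had 0.0296, and with the mitochondrial limit and lower UMI minimum Col1a1 had 0.37 and Plac8 0.24. Apart from the saturated G2/M share, the cause was not tested.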

Other observations

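The genes named in this part, and the tests of a shared clone, of chromosome gains and of a flanking segment, were chosen after the results had been seen. Further transcription factors changed in TCL1 nuclei. Foxp1 rose from 39.4 to 196 CPM (log2 fold change 2.32, edgeR adjusted p = 0.00112) and Bcl11a from 17.2 to 58.1 CPM (1.76, adjusted p = 0.00561), while Lmo2 fell from 71.3 to 14.7 CPM (-2.28, adjusted p = 0.00741). Serpine2 rose from 5.79 to 58.2 CPM and Pcdh9 from 189 to 512 CPM. Ptger4, a receptor for prostaglandin E2, fell from 39.0 to 6.68 CPM and Lmna from 104 to 28.6 CPM.

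Xist was seen in 0.626% and 0.263% of TCL1 nuclei in the WT-labelled libraries and in 3.86% and 2.25% in the KO-labelled libraries. Free RNA held Xist at 0.682 and 0.869 CPM in the WT-labelled and 13.4 and 16.1 CPM in the KO-labelled libraries, above its 4.72 and 4.60 CPM in TCL1 nuclei of the KO-labelled libraries. Xist was seen in 100% and 98.2% of erythroid cell-like nuclei, and in 92.3% and 59.0% (WT-labelled) and 62.5% and 77.8% (KO-labelled) of nuclei of the unnamed cluster. Plasma cell-like nuclei had it in 0 of 6 and 2 of 16.

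The shared leading immunoglobulin segments were set against 1 shared B cell clone. Ighv12-3 led in 4 of 4 libraries, which a shared clone needs, but Igkv2-107 differed by label (1.47% and 1.24% against 11.8% and 11.8%). A shared clone and separate clones with the same segment cannot be told apart without junction sequences.

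Whole chromosome gains or losses would shift many genes of a chromosome together, but the largest absolute median log2 fold change of a chromosome was 0.0791. A gain or loss in a small share of nuclei stays open. A segment inherited with the Tbx21 deletion that altered many of its genes would raise the share of called genes near Tbx21, but that share was 1.18 times the share elsewhere. A segment that alters few genes stays open, because this share could not show it. Of the 20 genes called within 10 Mb, those closest to Tbx21 all rose. They were Hoxb6 (at -806 kb, log2 fold change 3.08, edgeR adjusted p = 0.00622), Hoxb3 (at -775 kb, 2.14, 0.0390) and Npepps (at 108 kb, 0.69, 0.0469).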
